A study of Mus musculus with 6 samples.

How the data were processed

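Poly(A) RNA was sequenced from mouse neural stem cells of embryonic day 14.5 that carried a lentiviral short hairpin RNA (shRNA), in 6 libraries. Per the labels, 2 libraries carried a scrambled hairpin, 2 carried Sox4 shRNA 1 and 2 carried Sox4 shRNA 2, and the libraries of each group are numbered by passage. Libraries were made with the SOLiD Total RNA-Seq kit, per the labels' protocols. Nothing says that the passages were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

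The submitters' processing notes name TopHat2 2.0.9, Cufflinks 2.2.1, Cuffdiff without a version, and the mouse genome build mm10. The annotation the authors used, and whether strand was used in counting, are not given in the sources used here. The values analysed here are the authors' own comparison of a pair of conditions. Per the file headers, the deposited table gives each gene a level in the first and in the second condition, a log2 fold of second over first, a test statistic, which is a score, a p-value, a q-value and a flag for significance. The unit of the deposited levels is not stated in the header. Cuffdiff writes FPKM (fragments scaled to transcript length and to the number of mapped fragments) in such columns, and the plan fixed before the data were examined assumed FPKM for the deposited levels. The header does not name the conditions, and it does not say whether both Sox4 shRNAs were pooled. No condition was assigned from the values or from the order of the columns.

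The authors' deposited table holds 12316 gene rows with test status OK, besides 1 blank line. Of these rows, 82 name several genes and 166 carry a symbol that stands in several rows. No level is 0. A row at 300417 in the first and 301429 in the second condition held 37.6% and 38.9% of the summed levels. The q-values imply at least 14189 tests, so some of the authors' tests are not analysed here. The table holds no value per library. The sequencing depth is therefore unknown, no standard deviation or n can be given, and no test was refitted. A gene is termed called where the authors set their flag. The highest q among called rows is 0.0494 and the lowest among the others is 0.0504. The lowest p, 5e-05, is shared by 230 rows, which cannot be ranked by p.

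What was computed here starts from that table, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Gene lists, 49 in number, were fixed before the data were examined. Members were measured where the row names 1 gene and the level is at least 1 in the higher condition, and 11564 genes met the same criteria and served as the background. Of the lists, 46 had at least 3 measured members. For each, called members were counted in each direction, with the authors' q and with Benjamini-Hochberg values adjusted over the list alone. Called members were compared with the other background genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 92 tests. Genes are not independent replicates, so these tests describe this comparison only. The median log2 ratio, with a pseudocount of 1, was ranked among the medians of 10000 random lists of the same size matched on mean expression. A log2 ratio with a pseudocount understates the change of genes at low levels.

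Positions, transcript lengths and exon overlaps were taken from GENCODE release M21, on GRCm38, the assembly that the notes name as mm10. This is not stated to be the authors' annotation. Symbols of 11693 rows were found as written and 462 through an older name. Transcript length was that of the longest transcript, coding where the gene has one, and was known for 99.3% of background genes. After a trend of the log2 ratio with transcript length had been seen, each list was also compared with random lists matched on length and expression, after a smoothed length trend (span 0.3) was taken off. The one-sided permutation p of each list's called count among those lists was adjusted over the same 92 tests. Matching used 5 groups of length and 5 of expression, and the smoothed trend was taken off the log2 ratios, not off the calls. For the longest transcripts this matching was coarse: rises numbered 54 in the 9th and 159 in the last of 10 length groups. The steps were tested on simulated data of 11487 genes with 200 genes shifted by 0.4 in 10 lists. All 10 shifted lists passed the 97.5th percentile before and after the length trend was taken off. By Fisher's test 9 of them passed, and 0 of 10 lists without a shift did. A length slope of 0.3 per 10-fold was planted in the log2 ratios, but calls were not tied to length. Part of the shifted genes were set as called, so their passing of Fisher's test was largely built in. Lists were drawn without regard to length, so lists of mostly long or mostly short transcripts were not tested.

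The genes named in the text follow a rule set before the data were examined. It takes Sox4, Sox11, Sox12 and Hes5, then the 10 largest rises and the 10 largest falls among called genes with a level of at least 1 in the higher condition and a single symbol. From each list described it takes up to 4 called members with the largest fold, or up to 2 with the highest level where fewer than 2 were called. Some genes that the rule takes are not reported here. Other genes are said to have been chosen after their values were seen. Alternatives tried were a q of 0.01, a fold threshold, level filters, recomputed q-values, centring, other pseudocounts, single-symbol rows and the length treatments.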

Results

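Gene expression was compared in embryonic neural stem cells of CD-1 mice that carried a scrambled shRNA or 1 of 2 shRNAs against Sox4, a transcription factor of the SoxC group. Neural stem cells are dividing precursors that can give rise to neurons, astrocytes and oligodendrocytes. The cells were obtained commercially, came from E14.5 embryos and were grown as a monolayer on laminin with the growth factors EGF and bFGF, and selected with puromycin at 0.5 µg/mL after transduction. There were 2 libraries per hairpin, and the depth of each is unknown. The design asks which genes differ when Sox4 is targeted. The authors' comparison gives 1 level per condition and does not name the conditions, so each direction here is that of the second condition over the first. A gene that "rose" was called and higher in the second condition, and a gene that "fell" was called and lower there. Levels are in the unit of the deposited columns, which their header does not state.

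Sox4, the targeted gene (chromosome 13, 28948919 to 28953713, minus strand), stood at 126.8 in the first and 83.9 in the second condition in the authors' deposited table. Its log2 fold was -0.60 with a Cuffdiff q of 0.0543 in the authors' deposited table, so it was not called. With q recomputed over genes with a level of at least 1, it was 0.0463. Its exons overlap those of Gm26735 on the other strand, and reads of the 2 genes cannot be told apart unless strand was used. Of the other SoxC genes, Sox11 (chromosome 12, 27334264 to 27342574) rose from 12.6 to 20.1 in the authors' deposited table, a log2 fold of 0.67 with a q of 0.0135. Sox12 stood at 10.6 and 14.6 there, with a q of 0.167 in the authors' deposited table, and was not called. Adjusted over the list alone, 2 of the 3 SoxC genes passed as higher and 1, Sox4, as lower.

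Hes5, a transcriptional repressor induced by Notch signalling (chromosome 4, 154960923 to 154962371), fell from 37.3 to 14.4 in the authors' deposited table, 2.59-fold, with a q of 0.00304. Its exons overlap Gm20421 on the other strand. Over the whole of the authors' deposited table, 615 of 12316 gene rows were called, 390 of them higher and 225 lower in the second condition. Of these, 134 rose and 89 fell with an absolute log2 fold of at least 1. The median log2 fold of genes at 1 or more in both conditions was 0.0013, as computed here. The smallest absolute log2 fold among called rows was 0.55. Calls were not spread evenly over transcript length: among the longest 10% of transcripts 159 genes rose and 12 fell, and outside it 231 rose and 213 fell. The share of calls that were higher was 63.4% over all rows and 52.0% outside the longest 10%.

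**Figure D1:**
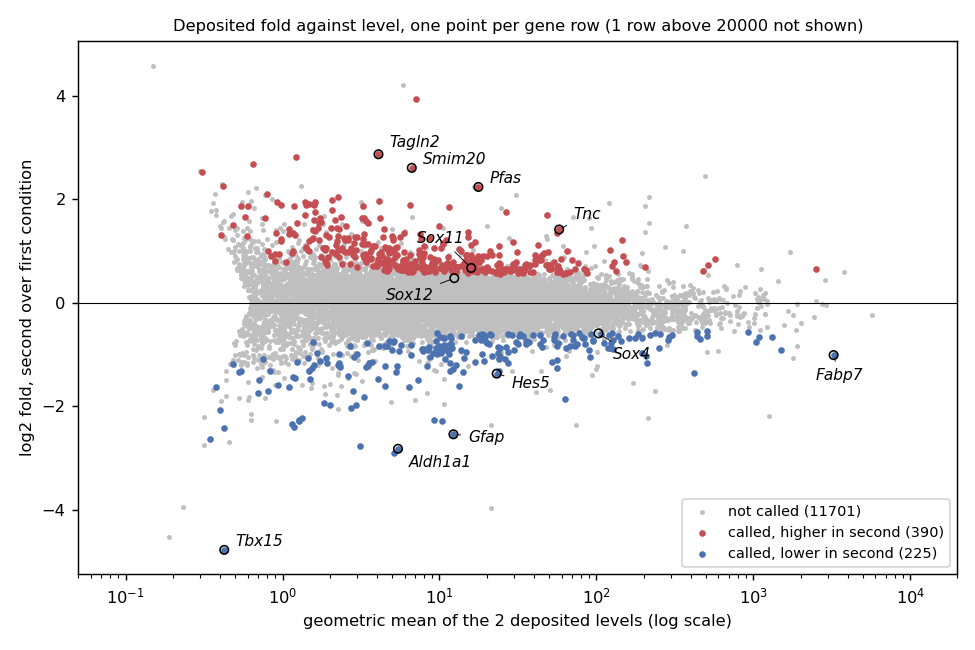
Log2 fold of the second over the first condition against the geometric mean of the 2 deposited levels on a log scale. There is 1 point per gene row, and red and blue points were called. The row with levels of 300417 and 301429 lies off the plot. The 390 red points and 225 blue points lie on both sides of 0, and Sox4, with a log2 fold of -0.60, is among the grey points.

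The largest rises came from genes of varied function. Tagln2, an actin-binding protein, rose 7.28-fold from a level of 1.51 in the authors' deposited table. Gypc, a membrane glycoprotein of red cells, rose 6.99-fold and Cpne7, a calcium-dependent phospholipid-binding protein, 6.37-fold in the authors' deposited table, both from levels under 1. Smim20 rose from 2.70 to 16.4 and Pfas, an enzyme of purine synthesis, from 8.17 to 38.4 in the authors' deposited table. Erich3, Cend1, Sp8, Fbln2 and Gm10825 rose between 3.86-fold and 4.28-fold in the authors' deposited table. Sp8 is a transcription factor of the developing forebrain and Fbln2 a matrix protein. Exons of Pfas overlap Mir3062, and those of Cpne7 overlap Mir7080.

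The largest falls included several glial genes. Tbx15, a T-box transcription factor, fell from 2.23 to 0.0811 in the authors' deposited table, a log2 fold of -4.78 with a q of 0.0199. Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102900912), fell from 29.7 to 5.08 in the authors' deposited table. Agt, the precursor of angiotensin, fell 4.87-fold and Aldh1a1, an enzyme of retinoic acid synthesis, 7.09-fold in the authors' deposited table. Twist1, a mesodermal transcription factor, the GABA-B receptor gene Gabbr2 and C1ql1 fell between 4.81-fold and 5.31-fold in the authors' deposited table. E030003E18Rik fell 6.86-fold and Hist1h2bk 7.55-fold in the authors' deposited table. Hist1h2bk belongs to a multi-copy histone family, whose reads can be split between near-identical genes. The libraries were of poly(A) RNA, so its level covers only the transcripts captured that way.

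Astrocyte genes were lower as a group. Of 24 measured members, 10 fell, 1 rose and 13 were not called, and adjusted over the list alone 13 were lower and 2 higher. Besides Gfap and Agt, the water channel gene Aqp4 fell from 8.27 to 3.52 in the authors' deposited table. Aldh1l1, an enzyme used as an astrocyte marker, went the other way, from 4.98 to 11.6 in the authors' deposited table. Exons of Aldh1l1 overlap Gm45901 on the same strand and Gm15756 on the other strand. The excess of falls had an adjusted p of 6.61e-10 by Fisher's exact test, and the median log2 ratio of -0.51 lay below all 10000 matched random lists. The members' median transcript length was 2936 nt. With random lists matched on length, the adjusted permutation p was 0.0046, the smallest these permutations can give.

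Notch target genes moved in a similar direction on fewer members. Of 11 measured, 4 fell and 1 rose, and adjusted over the list alone 6 were lower and 1 higher. Gfap and Hes5 were among those that fell, as was Fabp7, a fatty acid binding protein of radial glia, from 4620 to 2286 in the authors' deposited table. Tnc, which encodes the matrix protein tenascin C, rose from 35.5 to 94.5 in the authors' deposited table. The excess of falls had an adjusted p of 0.00084 by Fisher's exact test and of 0.0061 by permutation with length matching, at a median length of 2550 nt. This list shares Gfap with the astrocyte list. Of the 28 measured genes of the Notch pathway, 3 fell and 1 rose, with the same counts adjusted over the list alone. Hes5 and Nrarp, among these falls, are also falls of the target list. The adjusted p of the pathway falls was 0.124 by Fisher's exact test. Dll3, a Notch ligand, fell from 23.4 to 7.61 and the receptor gene Notch1 rose from 22.9 to 35.0 in the authors' deposited table.

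Extracellular matrix genes were higher as a group. Of 23 measured, 9 rose, 0 fell and 14 were not called, and adjusted over the list alone 10 were higher and 0 lower. Lamc1, a laminin chain (chromosome 1, 153218922 to 153332786), rose from 35.1 to 89.6 in the authors' deposited table. Fbln2 rose 3.92-fold, Tnc 2.66-fold and Hspg2, which encodes perlecan, 2.37-fold in the authors' deposited table. The adjusted p of the rises was 1.04e-06 by Fisher's exact test, and the median log2 ratio was 0.31. These are long transcripts, with a median of 7106 nt. With random lists matched on length, the adjusted permutation p was 0.0046. This matching was coarse among the longest transcripts, where rises were most frequent. Markers of fibroblasts and other mesenchymal cells were measured for 7 genes, of which 3 rose and 1 fell, with the same counts adjusted over the list alone. Their adjusted p was 0.0173 by Fisher's exact test and 0.0407 by permutation with length matching, at a median length of 2035 nt. Col5a1 and Fbn1, 2 of these 3 rises, are also among the 9 rises of the matrix list. Of the 5 markers outside that list 1 rose and 1 fell, and the adjusted p of the rises was 0.507 by Fisher's exact test. Acta2, a smooth muscle actin, rose from 29.4 to 55.8 and Twist1 fell from 2.73 to 0.515 in the authors' deposited table. Of the 3 abundant fibrillar collagen genes Col1a1, Col1a2 and Col3a1, 0 are among the rows analysed here. Genes of the response to TGF-beta had 4 rises and 1 fall among 14, and 5 and 1 adjusted over the list alone. Their adjusted p was 0.0164 by Fisher's exact test, and the call was lost with length matching, at an adjusted permutation p of 0.0685 and a median length of 5103 nt. Their median log2 ratio was 0.28 before and 0.25 after the length trend was taken off, and the latter lay at percentile 99.51 of the length-matched lists. Of these rises, Fn1 is also in the matrix list and Acta2 in the fibroblast list.

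Imprinted and growth-regulating genes included 5 rises and 0 falls among 12 measured, and 6 rises and 2 falls adjusted over the list alone. Peg10 rose from 16.4 to 35.2, Peg3 from 34.9 to 69.1 and Mest from 424 to 757 in the authors' deposited table. These 3 are expressed from the paternal allele. Igf2r, a receptor gene expressed from the maternal allele, rose from 3.44 to 6.69 in the authors' deposited table. The adjusted p of the rises was 0.00076 by Fisher's exact test and 0.0138 by permutation with length matching, at a median length of 4546 nt. Peg3 and Igf2r, of 8694 and 8887 nt, are among the longest transcripts, where this matching was coarse. Exons of Mest overlap Copg2 on the other strand.

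Replication genes of S phase leaned upward while genes of G2 and M phase did not. Of 30 S phase genes, 27 had a positive fold, but 4 rose and 0 fell, and adjusted over the list alone 5 were higher. Mcm2, a subunit of the replicative helicase, rose from 44.5 to 71.2, and its partner Mcm3 from 52.2 to 78.0, in the authors' deposited table. The median log2 ratio of 0.27 lay above all random lists. The rises had an adjusted p of 0.124 by Fisher's exact test and of 0.0184 by permutation with length matching, at a median length of 2984 nt. Of 29 G2 and M phase genes, 0 were called by the authors' Cuffdiff q or adjusted over the list alone, 1 had an unadjusted p under 0.05, and 10 had a positive fold. The difference between these lists was not tested.

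Markers of other lineages and of neural stem cells moved in part. Of 19 early oligodendrocyte lineage genes 3 fell and 0 rose, also adjusted over the list alone. These were Dll3, Lhfpl3 and Gpr17, a receptor of oligodendrocyte precursors that went from 22.7 to 8.90 in the authors' deposited table. Dll3 is also a fall of the Notch pathway list. Exons of Gpr17 overlap Lims2 on the other strand. The falls had an adjusted p of 0.0673 by Fisher's exact test and of 0.0383 by permutation with length matching, at a median length of 3715 nt. Among 14 myelin genes 2 fell and 1 rose, and adjusted over the list alone 6 were lower and 2 higher. Among them Trf, which encodes transferrin, rose from 2.10 to 5.28 in the authors' deposited table. Exons of Trf overlap Gm20425 on the same strand. Neuron and neuroblast genes had 1 rise, Sp8, and 1 fall, Elavl4, among 17, and 1 and 2 adjusted over the list alone. Among 25 neural stem and radial glia markers 4 rose and 3 fell, and 5 and 4 adjusted over the list alone. Their rises had an adjusted p of 0.0867 and their falls of 0.103 by Fisher's exact test. Fabp7 and Hes5, among these falls, are also falls of the Notch target list. Among the rises, Tnc is also in the matrix list and Notch1 in the Notch pathway list.

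**Figure D2:**
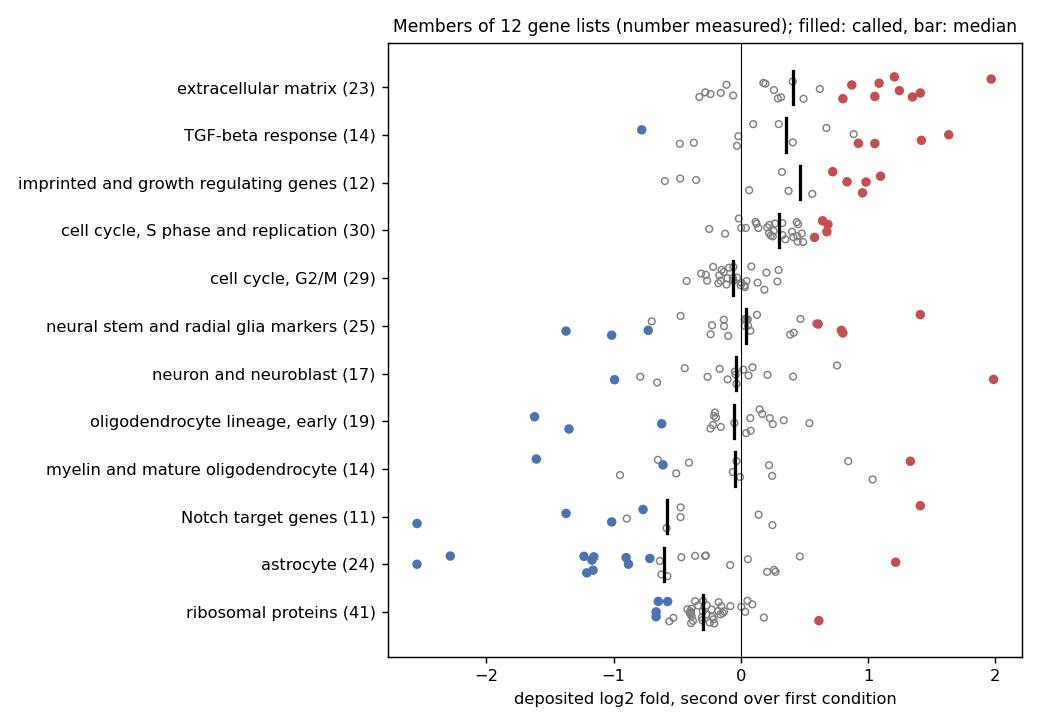
Deposited log2 fold of the second over the first condition for measured members of 12 gene lists, with 1 point per gene, filled where called, and a bar at the median of the deposited folds. Extracellular matrix genes have 9 filled points to the right of 0 and 0 to the left, and astrocyte genes have 10 to the left and 1 to the right.

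Ribosomal protein and histone genes had negative medians. Of 41 ribosomal protein genes 4 fell and 1 rose, also adjusted over the list alone, and 35 had a negative fold. The falls had an adjusted p of 0.0829 by Fisher's exact test and of 0.440 by permutation with length matching. These are short transcripts, with a median of 964 nt, and the median log2 ratio of -0.30 became -0.12 once the length trend was taken off. The latter still lay at percentile 1.42 of the length-matched lists. Rps20 fell from 1656 to 1044 and Rpl8 rose from 385 to 588 in the authors' deposited table. Exons of Rps20 overlap Gm24016 on the same strand. Genes of ribosome biogenesis leaned the other way, with a median log2 ratio of 0.15 and 19 of 24 positive, and 0 were called by Cuffdiff, with 7 at an unadjusted p under 0.05. Of 16 histone genes 2 fell and 0 rose in these libraries of poly(A) RNA. Adjusted over the list alone 6 were lower, at a median length of 1472 nt. The falls of the histone genes had an adjusted p of 0.205 by Fisher's exact test and of 0.251 by permutation with length matching. Their median log2 ratio was -0.44 before and -0.30 after the length trend was taken off. The latter lay at percentile 0.01 of the length-matched lists. Among 13 BMP and Id genes 2 fell and 0 rose, and adjusted over the list alone 4 were lower and 2 higher. Id2, an inhibitor of basic helix-loop-helix factors, fell from 81.9 to 38.0 in the authors' deposited table, and the adjusted p of the falls was 0.170 by Fisher's exact test. Id3, the other fall, is also a fall of the astrocyte list.

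**Figure D3:**
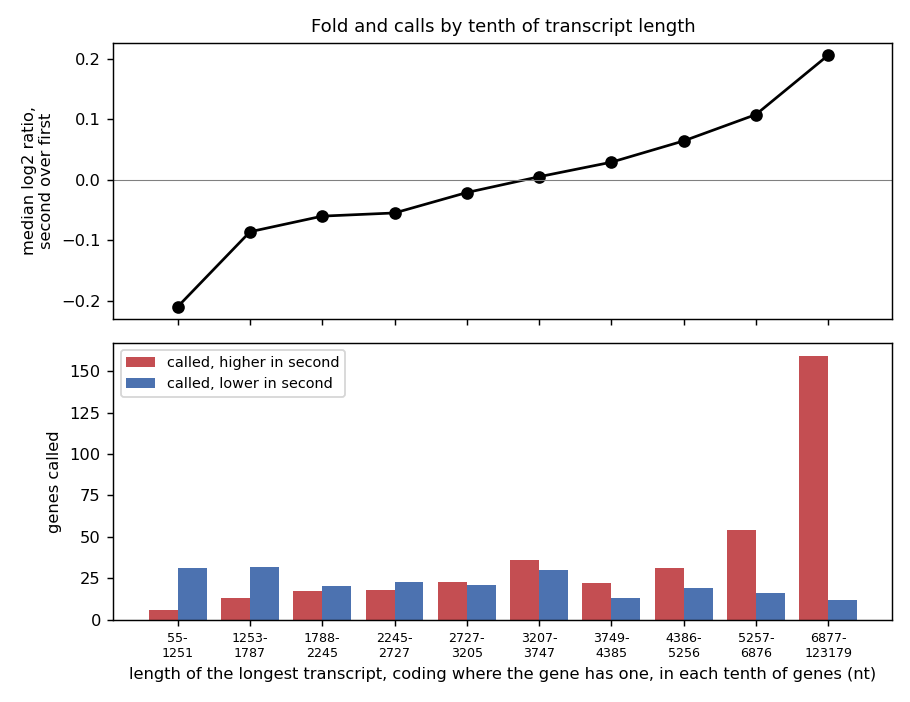
Median log2 ratio, with a pseudocount of 1, and number of called genes in 10 groups of genes ordered by transcript length in nucleotides. The median goes from -0.21 in the shortest group to 0.21 in the longest, where 159 genes rose and 12 fell.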

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

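The tests that leave out the longest transcripts, take off the length trend, leave shared members out of the fibroblast list or recompute the q of Sox4 were chosen after the data were seen, and the others before. The counts of 390 rises and 225 falls became 203 and 110 at a q of 0.01, and 134 and 89 with an absolute log2 fold of at least 1, as a stricter threshold must give. Without the longest 10% of transcripts the rises were 231, and the falls stayed within 1.5 times at 213. Level filters, recomputed q-values and single-symbol rows left both counts within 1.5 times. So did centring and keeping only calls whose sign held without the length trend, but these could hardly change a count. The smallest absolute log2 fold called was 0.55, against a centring of 0.0013 and medians from -0.21 to 0.21 over the length groups. Leaving out rows at 0 removed nothing, so it tests nothing. The q of Sox4 went from 0.0543 to 0.0463 when recomputed over fewer genes. A pseudocount cannot change the sign of a fold, so the kept sign of Sox4 with both pseudocounts tests nothing. Of 61 list counts, 0 changed side of Fisher's threshold under a filter of 5 or no filter. The 3 rises among fibroblast markers became 1 without members of the extracellular matrix list, and the call was lost with fewer genes. Of 276 alternative list medians, 0 changed the sign of a list that stood apart from random lists, and 4 moved beyond their bootstrap interval, each with the length trend taken off. Likewise 0 of 132 other named genes changed sign with a pseudocount, which was fixed in advance. Of these genes, 18 lost over 1.5 times of their log2 fold with a pseudocount of 1. No paired analysis was possible because the table holds 1 level per condition, with no values for the numbered passages. For the same reason leaving out each replicate and the block on passage were not run. The agreement of the 2 shRNAs was not run because the table holds 1 comparison. The depth is unknown, so it sets no stated limit.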

Other observations

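Further lists fixed before the data were examined give a few groups not described so far. Cholesterol synthesis genes had 2 rises and 0 falls among 22, a median log2 ratio of 0.21 and a percentile of 99.98 among random lists. Their rises had an adjusted p of 0.516 by Fisher's exact test and of 0.161 by permutation with length matching. Lss, an enzyme of sterol synthesis, rose from 44.4 to 79.2 in the authors' deposited table. Among 21 glycolysis and hypoxia genes Hk2, a hexokinase, rose from 3.59 to 8.64 in the authors' deposited table. Apoptosis regulators had 0 calls among 20 by the authors' Cuffdiff q and 0 at an unadjusted p under 0.05, and p53 targets had 1 fall among 24. Of 108 rows of microRNAs and small nucleolar RNAs, 0 were called by Cuffdiff and 1 had an unadjusted p under 0.05. As poly(A) RNA was sequenced, this does not show that these small RNAs were unchanged.

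Some genes were chosen after their values were seen. All 4 Hoxa genes in the table had a negative fold, and Hoxa5 fell 3.96-fold in the authors' deposited table. Hoxa4 stood at 3.45 and 1.01 there, with a q of 0.0535 in the authors' deposited table, and was not called. Xist, a transcript of 17946 nt, rose 3.24-fold from 0.772 in the authors' deposited table. The log2 folds of the Y-linked genes Eif2s3y, Ddx3y and Uty were -0.54, -0.34 and -0.32 there, and that of Kdm5d was 0.20. These Y-linked genes were not called, with Cuffdiff q-values from 0.112 to 0.690 in the authors' deposited table. Median log2 ratios of the 19 autosomes ran from -0.066 to 0.026, against 0.58 for a change from 2 copies to 3.

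All tests of explanations that follow, except that of GC content, were chosen after the result they measure had been seen. The plain correlation with GC content was known by then too. Transcript length went with the fold. Across 11487 genes, which are not independent replicates, the rank correlation was 0.33. Greater power for long transcripts would alone add calls both ways. Of the 171 calls in the longest 10% of transcripts 93.0% were higher, against 51.8% of the 425 other calls of known length (Fisher's exact test, two-sided, p = 1.62e-24). This argues against power as the whole cause. Power may still have added calls there, since that group had a median log2 ratio of 0.21, where more power adds mostly rises. GC content as the whole cause is argued against too, since the rank correlation was 0.40 once it was taken off. RNA integrity or fragment length may differ between the conditions: genes that were not called show a rank correlation of 0.31, as such a cause needs, but without values per library it cannot be told apart from an effect of the shRNAs, which is untested.

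For the rise of extracellular matrix genes, the length trend is argued against as the whole cause. With the trend taken off, their median log2 ratio was 0.30, above the 0.14 that bounds the upper end of 95% of random lists matched on length. Mesenchymal cells in the culture may contribute. The 5 fibroblast markers outside the matrix list had a median of 0.21, with 1 rise and 1 fall, and the abundant fibrillar collagens are not analysed here, so this stays open. An effect of the shRNAs is open too, and untested, since the conditions are unnamed.

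For the fall of astrocyte genes, the length trend is again argued against as the whole cause, with a median of -0.45 once it was taken off, below the -0.12 that bounds the lower end of 95% of random lists. Whether the fall has to do with the Sox4 shRNAs stays open, because the header names neither condition. It is also not stated that the comparison is of Sox4 shRNA with the scrambled control.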
